A study of Mus musculus with 2 samples.

How the data were processed

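Total RNA was measured in vesicle fractions from the culture medium of mouse cytotoxic T lymphocytes (CTL), the T cells that kill infected or tumour cells. Per the labels' protocols, cells were cultured for 7 days, the medium was concentrated and depleted of protein by ultrafiltration with a 750 kDa cutoff, and the concentrate was separated on a DEAE column. DEAE is a positively charged resin, so particles with more negative surface charge need more salt to leave it. The labels name a fraction eluted with 0.3 M NaCl and a fraction eluted with 0.5 M NaCl. RNA was amplified with an amino allyl kit and labelled with Cy5, per the labels' protocols, and each fraction was hybridised to 1 single-colour array. The mouse strain, the stimulus given to the cells and the number of preparations behind each fraction are not given in the sources used here.

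The deposited values are probe intensities on a linear scale, rounded to whole numbers. The scanner, the background correction, the normalization by the authors and the rule that left cells of the table empty are not given in the sources used here. The median over all probes with a value was 25 on both deposited columns. Over probes with a value on both arrays the medians were 32 at 0.3 M and 26 at 0.5 M, so the columns share a centre only when each is taken over its own set of probes. Empty cells were treated as having no value, and no floor was put in their place. The table holds 23473 probes. Of these, 20690 carried 1 gene symbol, 0 carried several and 2783 carried none in the annotation used here. Symbols were looked up by Entrez identifier for 20556 probes and by accession for 9 in a RefSeq gene table of assembly GRCm38.p6, and 125 kept the symbol of the array annotation. That lookup updated 8 symbols. No genome build is named for the array, so no coordinates are given.

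Choices described here were made before the data were examined unless said otherwise. Intensities were log2-transformed. Since the medians over shared probes differed by more than 0.1, each array's median over those probes was subtracted, which took out a shift of -0.30 (0.5 M minus 0.3 M). A gene was the mean of its probes measured on both arrays. A gene was kept if it lay at or above the median of measured genes on at least 1 array, which left 7446 of 13735 genes. Differences are log2 values at 0.5 M minus 0.3 M. With 1 array per fraction there is no test, no p-value and no standard deviation between replicates, and the number of arrays limits the precision of every value. A size rule of 2-fold was used to count genes. The disagreement between different probes of the same gene was the only error that could be estimated, and it leaves out the variation between vesicle preparations.

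Gene lists numbered 38 and were fixed in advance. They covered cytotoxic effectors, T cell receptor and signalling genes, T cell transcription factors, inhibitory and costimulatory receptors, cytokines, cytokine receptors, chemokines with their receptors, tetraspanins and vesicle membrane proteins, ESCRT and vesicle biogenesis genes, RNA-binding proteins of small RNA pathways, cytosolic ribosomal proteins, translation factors, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes, glycolysis, the proteasome, MHC class I, the cell cycle, histones, nuclear long noncoding RNAs, the cytoskeleton, interferon-stimulated genes, heat shock genes and apoptosis. Markers of other cells covered B cells, macrophages and dendritic cells with MHC class II, neutrophils with mast cells, NK cells, helper and regulatory T cells, red cells and platelets, fibroblasts and endothelium, liver, and neurons. Olfactory and vomeronasal receptors, keratins, zinc finger genes named Zfp and endogenous retroviral genes completed the set. The median difference of each list with at least 5 kept genes was placed among the medians of 10000 random lists of the same size, matched on level in 20 bins. A list is described as outside the random range if it lay in the outer 2.5% on either side. Near-identical copies (H4 and H2A histone genes, globins) can bind each other's probes. Granzymes and MHC class II chains are related rather than near-identical, and shared binding of their probes was not checked. Members of any of these families are not taken as independent.

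Genes were named by a fixed rule. It took the 12 kept genes with the largest difference in each direction whose level was in the top 25% of the brighter array and whose probes lay on the same side of 0, passing over predicted and RIKEN names. It added up to 3 of the brightest genes with a value on a single array, up to 4 kept members of each list with the largest absolute difference, and Cd8a, Cd3e, Gzmb, Prf1, Ifng, Cd63, Cd9, Cd81, Actb, Gapdh and B2m whatever their values. Alternatives were the values as deposited, quantile normalization, removal of a loess trend of the difference on level (span 0.3), no filter on dim genes, a stricter filter (at or above the median on both arrays), a pseudocount equal to each array's lower quartile (11 and 12), the brightest probe in place of the mean, a 4-fold rule, measurement called only above the 10th percentile, and random lists not matched on level. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. The steps were tested on simulated data for the comparison of 0.5 M with 0.3 M. In the full table of 23473 probes, 200 probes changed 4-fold were recovered within 0.05 log2 units. No noise was added, so this checks only the arithmetic. Over 7446 genes, a shift of 0.5 log2 units put 82.5% of 40 simulated lists of 10 genes and 100% of those of 40 genes above the random range, against 5% and 2.5% with no shift. Genes were shuffled singly within bins of level, so the simulated lists lack the shared variation of gene families.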

Results

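RNA of vesicles released by mouse cytotoxic T lymphocytes was measured in 2 fractions that left an anion exchange column at 0.3 M and at 0.5 M NaCl, with 1 array for each. There are no replicates, so every difference below describes this pair of arrays. A value was present for 18969 of 23473 probes (80.8%) at 0.3 M and for 16732 (71.3%) at 0.5 M. Both arrays had a value for 16154 probes (68.8%), the 0.3 M array alone for 2815, the 0.5 M array alone for 578 and neither for 3926. Intensities ran from 4 to 167286 at 0.3 M and from 5 to 251376 at 0.5 M, with quartiles of 11 and 70 against 12 and 69. Empty cells lay among dim probes. Of the 6076 probes at 50 or more at 0.3 M, 0 were empty at 0.5 M, whereas of the 3973 probes under 10 at 0.3 M, 2259 (56.9%) were empty at 0.5 M. In the other direction, of the 3088 probes under 10 at 0.5 M, only 503 (16.3%) were empty at 0.3 M. Dim probes were thus left empty unequally on the 2 arrays, for a reason not known, which limits every comparison of dim genes.

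The comparison asked whether vesicles that elute at different salt, and so differ in surface charge, hold different messenger RNAs. Their RNA profiles were alike in broad outline. Across the 7446 kept genes, which are not independent replicates, Pearson's r was 0.954 and Spearman's rho 0.911. With centring, the lists of respiratory chain, ribosomal protein, histone, cytotoxic effector and B cell genes had medians above the range of random lists at 0.5 M. So did the list that holds MHC class II genes. The list of red cell and platelet markers, mostly globin genes, had a median below that range. These lists kept their direction with quantile normalization and with loess, and the constant shift of the values as deposited was too small to turn them. Some came back inside the range in other settings. Among them were cytosolic ribosomal proteins with loess (percentile 86.1), cytotoxic effectors with the stricter filter (92.6) and B cell markers with no filter (89.8).

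At least 2-fold higher at 0.5 M were 390 genes and at least 2-fold lower 175, together 7.59% of those kept, and 69.0% of them were higher. That split rests on the scaling. It was 121 higher against 579 lower (17.3% higher) with the values as deposited, 253 against 286 (46.9%) with quantile normalization and 247 against 284 (46.5%) with loess. The median difference of all kept genes was 0.08 with centring and -0.22 as deposited, and differences are best read relative to it. Among the 10% of kept genes with the highest level the median difference was 0.46, against -0.04 among the 10% with the lowest. A spread between probes could be had for 358 kept genes with several probes. Its SD was 0.55, close to the SD of 0.56 of the differences of all kept genes. Paired probes of the same gene had differences that correlated at r = 0.06 and rho = 0.08 over 348 genes. Over the 55 pairs with both probes bright, r was 0.22, rho 0.24 and the SD 0.50. A normal spread would place 7.26% of genes beyond 2-fold with the SD of all pairs and 4.84% with that of bright pairs, so single differences near 2-fold were not separable from probe noise. The gene lists carry most of the comparison.

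**Figure D1:**
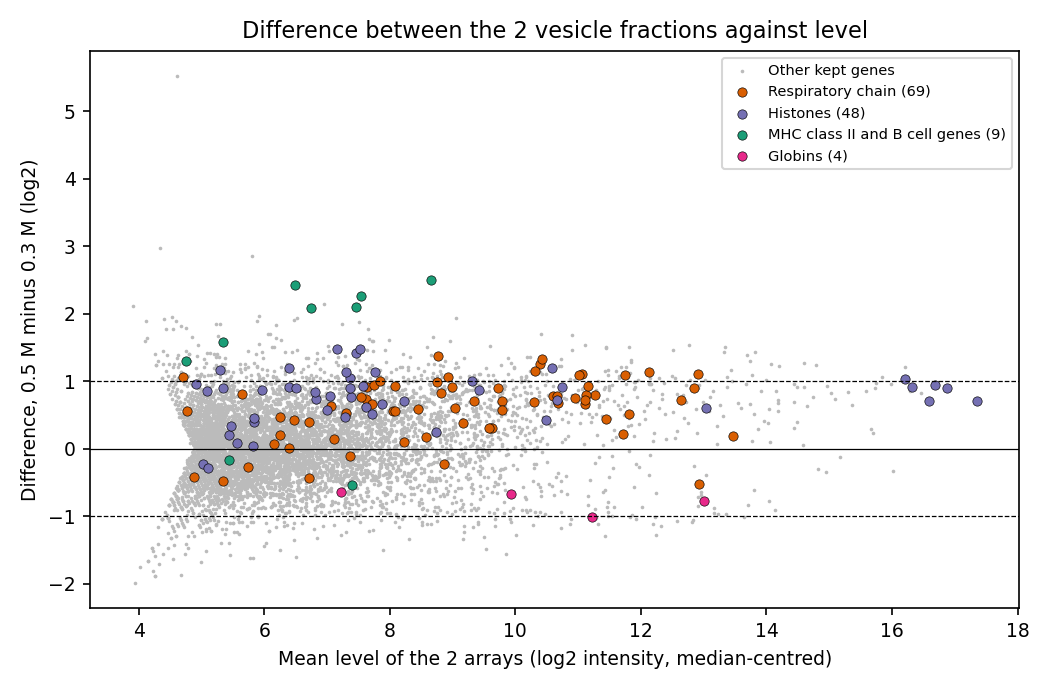
Each point is a kept gene, with its mean log2 level over both arrays on the x axis and its centred log2 difference (0.5 M minus 0.3 M) on the y axis, dashed lines mark 2-fold, and colours mark respiratory chain, histone, MHC class II with B cell, and globin genes. Of 7446 genes, 390 lie above and 175 below the lines, a split that turns to 121 and 579 with the values as deposited, and the brightest genes lie higher than the rest.

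Antxr2, a receptor for anthrax toxin, had the largest difference, 5.52, from an intensity of 4 at 0.3 M to 149 at 0.5 M. The first of these was the lowest intensity on its array, and a pseudocount lowered the difference to 3.60. Several MHC class II genes, which present peptides to helper T cells, were among the next. H2-Aa went from 188 to 863 (5.65-fold after centring), H2-Ea from 94 to 368 (4.82-fold) and H2-Eb1 from 58 to 200 (4.24-fold). Cd74, the invariant chain that escorts class II molecules, went from 43 to 188 (5.38-fold). Cd79b, a signalling chain of the B cell receptor, went from 94 to 328 (4.29-fold). Other class II genes, picked out after their values were seen, were the H2-Aa partner H2-Ab1, dim at 13 and 15, H2-DMb1 (0.68), H2-DMa (1.42) and H2-Ob (29 to 27, 0.20). These genes were ranked among those bright enough for the naming rule. The others among the 12 largest were the arginine methyltransferase Prmt2 (2.85), the actin regulator Jmy (2.15) and Myct1 (1.97). The cholesterol synthesis enzyme Dhcr7 (1.94), the tight junction protein Cldn5 (1.94) and the calcium channel subunit Cacng4 (1.91) completed them. Dimmer kept genes, such as Arsj (1.96) and Anapc2 (1.92), lay above some of these. The 4-fold rule left 10 genes higher and 0 lower. That split was 9 and 1 with quantile normalization, 9 and 0 with loess, but 5 and 7 with the values as deposited.

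Lower at 0.5 M were Zfp53 (-1.62), the defensin Defb9 (-1.61), the heparan sulfate proteoglycan Sdc3 (-1.61) and the receptor Adgrg7 (-1.57). Ptpn23, a phosphatase of the endosomal sorting pathway, went from 1765 to 488 (-1.56). Next came the olfactory receptor Olfr1148 (-1.51), Ssx2ip (-1.50), the serotonin receptor Htr6 (-1.44) and the thrombin receptor F2r (-1.40). The formin Fmnl2 (-1.35), Tcta (-1.33) and Vsig8 (-1.33) completed the 12 largest among genes bright enough for the naming rule. Some dimmer kept genes were lower still, such as Erbin (-1.98) and Cdc37l1 (-1.89). Of the genes past 2-fold in either direction, 54 had predicted or RIKEN names and are not listed. Only 1 had several probes.

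Of the 35 gene lists with enough kept genes, 8 lay above and 2 below the random range. By chance 1.75 would be expected if the genes of a list varied independently. Genes of a family do not, so such lists can leave the range more often. The excess of the 10 lists outside over 1.75 therefore cannot be weighed. Under quantile normalization and loess, 0 of these 10 changed the sign of their median, though its size and the number of members past 2-fold often did change. The values as deposited move each median by the same -0.30, too little to turn any of them.

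**Figure D2:**
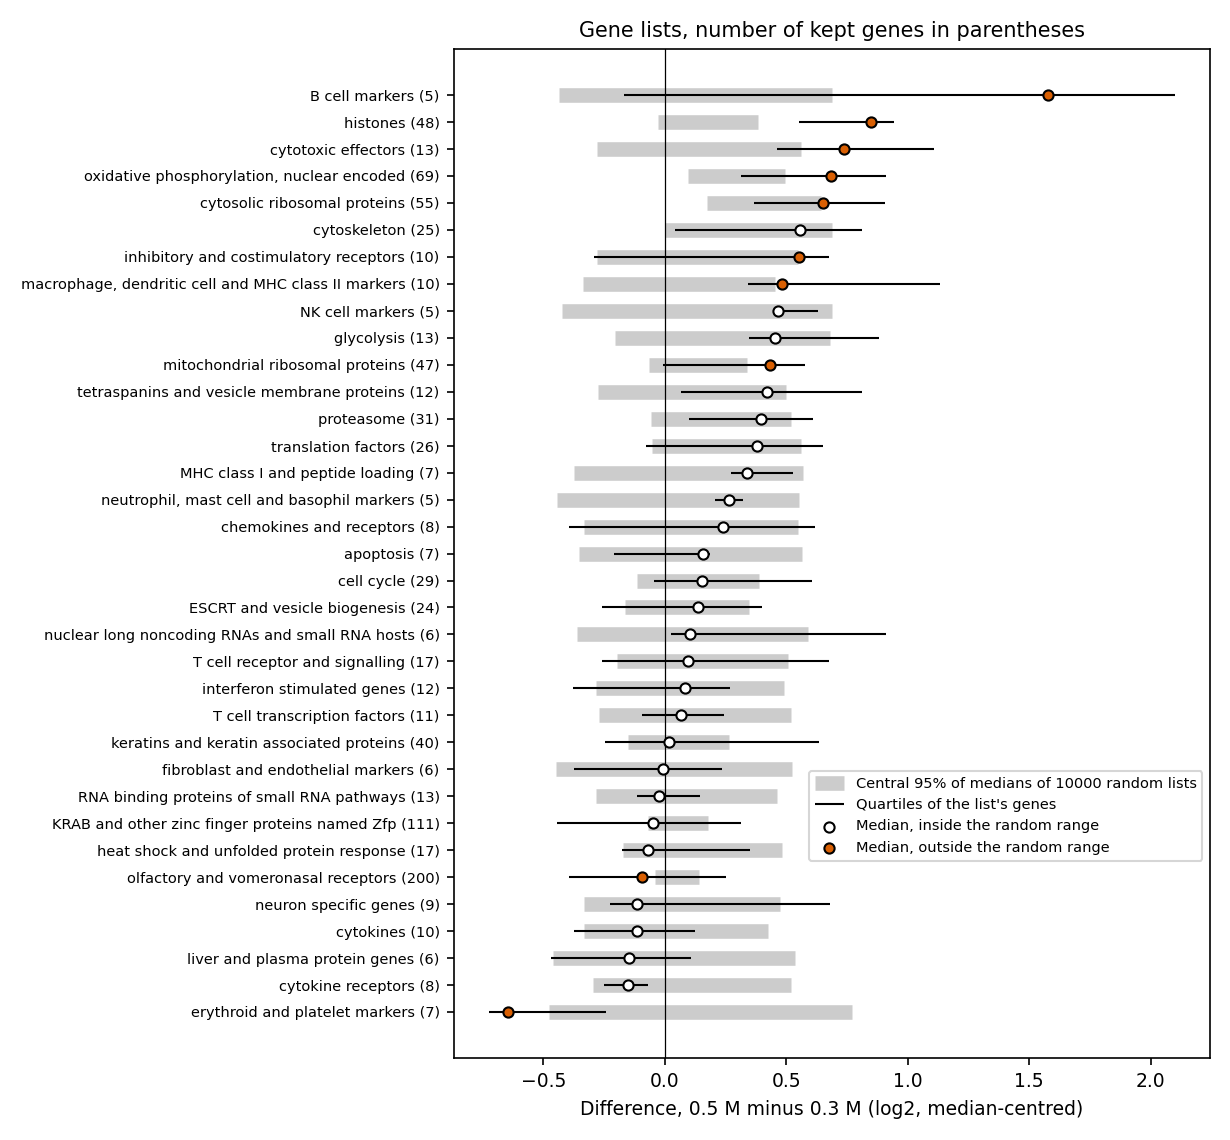
Each marker is the median centred log2 difference (0.5 M minus 0.3 M) of a gene list, with the quartiles of its genes, beside a grey bar for the range that holds 95% of random lists of matched level, and is filled if outside it. B cell markers, histones and cytotoxic effectors lie furthest to the right and red cell and platelet markers furthest to the left, though B cell markers are at 0.30 with no filter on dim genes, and the 10 lists outside the random range kept their sign under every scaling tried.

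Respiratory chain genes and ribosomal protein genes of mitochondria and cytosol had higher medians at 0.5 M, under every scaling tried. The nuclear-encoded subunits of the respiratory chain and ATP synthase, which make ATP in mitochondria, had a median difference of 0.68 over 69 genes, and 62 lay above 0. That median exceeded those of all random lists (percentile 100). At least 2-fold higher were 11 and at least 2-fold lower 0, against 2 higher as deposited, 2 with quantile normalization (median 0.40), 3 with loess (median 0.41) and 5 with a pseudocount. The complex I subunits Ndufa7 (300 to 631, 1.37), Ndufv3 (967 to 1970, 1.33), Ndufa6 (966 to 1868, 1.25) and Ndufb7 (943 to 1704, 1.15) had the largest differences. Mitochondrial ribosomal proteins had a median of 0.43 over 47 genes (percentile 99.8), with 1 gene past 2-fold, Mrps24 (848 to 1391, 1.01), ahead of Mrpl36 (0.92) and Mrpl54 (0.91). Their median was 0.25 with quantile normalization and with loess, and 0.13 as deposited, with 0 genes past 2-fold in each. Cytosolic ribosomal proteins had a median of 0.65 over 55 genes (percentile 98.2), with 50 above 0 and 5 past 2-fold. Rpl36 (9732 to 21396, 1.44), Rps10 (12319 to 23886, 1.25), Rps15 (1.12) and Rps18 (45013 to 76221, 1.06) led them. The median was 0.30 with quantile normalization and 0.23 with loess, with 0 genes past 2-fold in either, and 0.35 as deposited, with 1. With loess the list came back inside the random range (percentile 86.1), and Rps18 had a difference of 0.41. With quantile normalization Rps10 was at 0.65 and Rps18 at 0.41.

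Histone genes, which package DNA and are mostly made during DNA replication, had a median of 0.85 over 48 genes, above all random lists (percentile 100) and positive under every scaling tried. Of the 48, 46 lay above 0, 11 were at least 2-fold higher and 0 were lower. Past 2-fold were 6 with quantile normalization (median 0.52) and with loess (0.55), 3 as deposited (0.55) and 4 with a pseudocount. The 13 histone genes among the brightest 10% of kept genes had a median of 0.91 (percentile 97.3), and with loess 0.24 (percentile 63.6) with 0 past 2-fold, so these were not separable from the trend with intensity. H4c12 (95 to 215, 1.48), H4c6 (123 to 278, 1.48), H4c2 (119 to 259, 1.42) and the linker histone H1f8 (1120 to 2093, 1.20) had the largest differences. The H4 genes encode the same protein from closely similar sequences, so their probes may not separate them. Cell cycle genes lay inside the random range. Their median was 0.15 over 29 genes (percentile 59.2) and below 0 under the other scalings, with Rrm2, a subunit of ribonucleotide reductase, at -0.95 and the mitotic kinase Aurkb at 0.88.

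Cytotoxic effector genes, the killing machinery of these cells, had a median of 0.74 over 13 genes (percentile 99.8), with 11 above 0 and 6 at least 2-fold higher, and stayed positive under every scaling tried. Only 1 passed 2-fold as deposited (median 0.44) and 1 with a pseudocount. Granzymes, the proteases of cytotoxic granules, led with Gzmg (135 to 330, 1.59) and the dim Gzmd (32 to 58, 1.16) and Gzmm (24 to 42, 1.11), along with the protease Ctsw (43 to 82, 1.23). Gzmb, an abundant granzyme, went from 2493 to 2838 (0.49). Prf1, the pore-forming perforin, went from 33 to 26 (-0.04) and Ifng, a cytokine, from 468 to 238 (-0.68), so its members lay on both sides of 0. The stricter filter left 9 genes and brought the list inside the random range (percentile 92.6). Inhibitory and costimulatory receptors had a median of 0.55 over 10 genes (percentile 97.6), positive under every scaling but inside the random range with quantile normalization (96.2, median 0.37) and loess (96.8). Members lay on both sides of 0, with Tnfrsf18, known as GITR, from 923 to 1630 (1.12) and Tnfrsf4, known as OX40, at 0.85, against Cd244a from 63 to 16 (-1.68) and Icos from 155 to 67 (-0.91).

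Genes of T cell identity stayed near the median of all genes. T cell receptor and signalling genes had a median of 0.10 over 17 genes (percentile 37.6), negative under the other scalings. Without the filter on dim genes it was 0.52 over 20 genes (percentile 99.2). The receptor chains Cd3g (105 to 162, 0.93) and Cd8b1 (333 to 496, 0.87) and the kinase Txk (1.15) stood against the adaptor Lat (294 to 129, -0.89). Cd8a, the coreceptor that marks these cells, went from 3677 to 2463 (-0.28), and Cd3e was dim on both arrays (12 and 14). T cell transcription factors had a median of 0.07 over 11 genes (percentile 42.0), negative under the other scalings. Tbx21, the master regulator known as T-bet, was very bright, at 39433 and 25174 (-0.35, and -0.91 with quantile normalization and -0.94 with loess), while Batf was at 0.82.

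Lists of B cell markers and of macrophage, dendritic cell and MHC class II markers had medians above 0 under every scaling tried, with members on both sides of 0. B cell markers had a median of 1.58 over only 5 kept genes (percentile 100), 3 of them at least 2-fold higher. These were Cd74, Cd79b and the adaptor Blnk (26 to 63, 1.58), while the B cell coreceptor Cd22 went from 225 to 126 (-0.54). With 9 genes and no filter on dim genes the median was only 0.30, the size of the shift between arrays, and the percentile 89.8. Markers of macrophages, dendritic cells and MHC class II had a median of 0.48 over 10 genes (percentile 98.3), with 3 at least 2-fold higher, all of them class II genes or their activator Ciita (19 to 38, 1.30), and 1 lower. That gene was the macrophage mannose receptor Mrc1 (259 to 87, -1.27). The median was 0.18 as deposited, and the percentile was 96.8 with the stricter filter and 97.3 with random lists not matched on level.

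The list of red cell and platelet markers had a median below 0 under every scaling tried. It was -0.65 over 7 genes (percentile 0.66), although only 1 gene passed 2-fold. Of the 7, 4 were globin genes, whose products carry oxygen. The median was that of the globin Hbb-b2, so it says little about other red cell or platelet genes. The dim red cell gene Alas2, at 0.30, was the only member above 0. Hbb-bs went from 3747 to 1518 (2.01-fold lower after centring), Hba-a2 from 12001 to 5681 (-0.78), Hbb-bt from 1367 to 697 (-0.67) and Hbb-b2 from 208 to 108 (-0.65). Globin sequences are alike enough to share probes. Olfactory and vomeronasal receptors, made in sensory neurons, had a median of -0.09 over 200 genes (percentile 0.065), negative under every scaling tried, with 14 at least 2-fold lower and 8 higher. The split was 17 lower against 6 higher with quantile normalization, 17 against 5 with loess and 26 against 4 as deposited, with medians of -0.14, -0.14 and -0.39. A list of genes from other cells thus left the random range at a small median. Lying outside that range is therefore not by itself a sign of different vesicle RNA. Olfr830 (-1.59) stood against Olfr802 (14 to 42, 1.88), Olfr432 (1.84) and Olfr806 (120 to 335, 1.78), and with a pseudocount Olfr830 was at -0.95 and Olfr802 at 1.29.

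**Figure D3:**
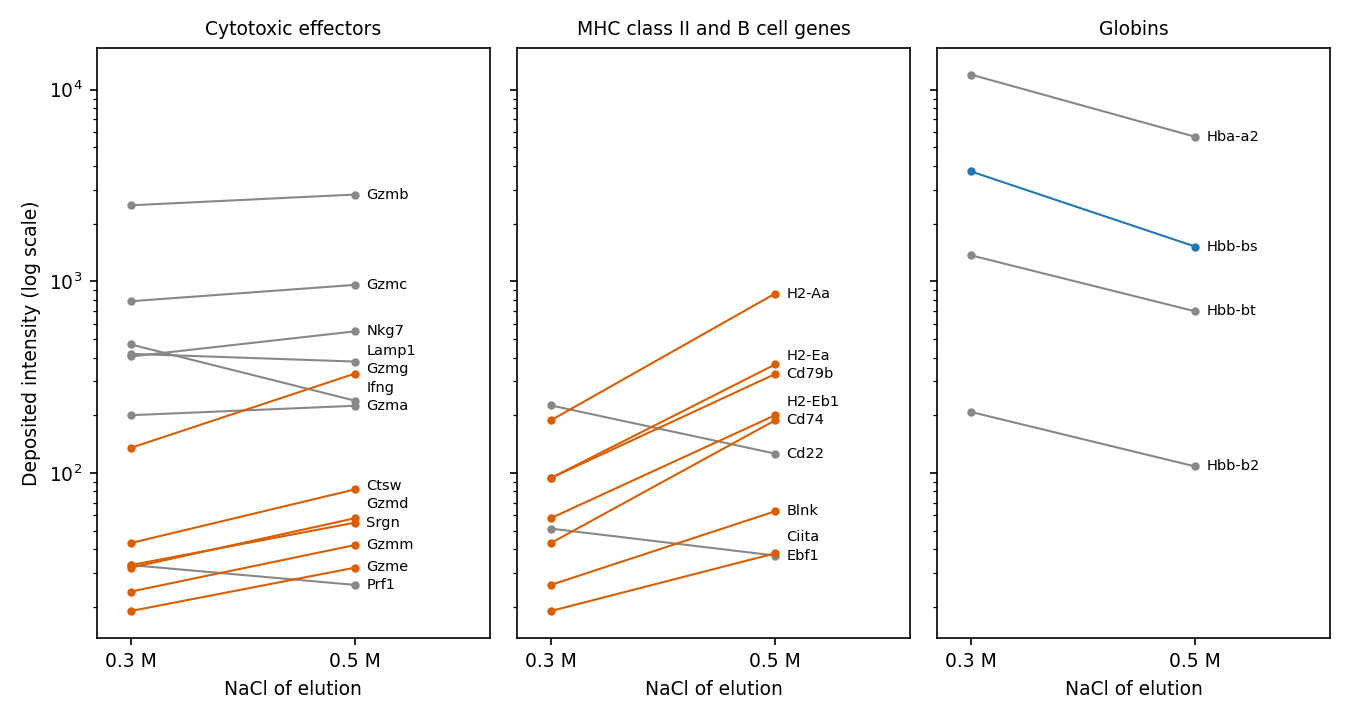
Each pair of points gives the deposited intensities of a gene at 0.3 M and 0.5 M NaCl on a log axis, with 1 array per fraction and no error bars, coloured orange if at least 2-fold higher after centring, blue if at least 2-fold lower and grey otherwise. H2-Aa (188 to 863) and Gzmg (135 to 330) are higher at 0.5 M and Hbb-bs (3747 to 1518) is lower.

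Genes of vesicle formation lay inside the random range with centring. Tetraspanins and other vesicle membrane proteins had a median of 0.42 over 12 genes (percentile 93.9), with 3 at least 2-fold higher, the tetraspanin Cd37 (150 to 278, 1.19), the glycoprotein Bsg (161 to 282, 1.11) and the membrane-binding Anxa2 (2167 to 3761, 1.09). The list lay above the random range with quantile normalization (percentile 98.9), loess (97.8) and no filter on dim genes (99.8). Of the tetraspanins commonly used as vesicle markers, Cd81 went from 51 to 68 (0.71), whereas Cd63 (16 and 12) and Cd9 (11 and 12) were dim on both arrays. ESCRT and vesicle biogenesis genes had a median of 0.14 over 24 genes (percentile 64.5), negative as deposited. Vps37b (40 to 13, -1.32) and Tsg101 (423 to 211, -0.70), both of the ESCRT-I complex, stood against Vps28 (0.82), also of that complex. RNA-binding proteins of small RNA pathways had a median of -0.02 over 13 genes (percentile 28.2), with Dicer1 at -0.83 and Ybx1 at 0.42.

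Signalling proteins also lay inside the random range. Chemokines and their receptors had a median of 0.24 over 8 genes (percentile 72.7), negative as deposited. Ccl5, a chemokine secreted by activated T cells, went from 258 to 661 (1.66) and the receptor Ccr4 from 2007 to 3270. Cytokines had a median of -0.12 over 10 genes (percentile 23.1), with Tnfsf14 at -0.63 and Csf2 at 0.54, and cytokine receptors -0.15 over 8 (percentile 11.1), with Il2rb at 0.46. Interferon-stimulated genes had a median of 0.08 over 12 genes (percentile 45.7), negative under the other scalings, with Gbp3 from 40 to 11 (-1.56, and -0.97 with a pseudocount) and Rtp4 from 5774 to 2367 (-0.99).

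Other lists of metabolism and structure had positive medians inside the random range. Glycolysis genes had a median of 0.45 over 13 genes (percentile 82.6) and all 13 lay above 0 after centring, led by Aldoa (13614 to 25997, 1.23) and Aldoc (1.09), with Gapdh from 119 to 178 (0.88). The cytoskeleton had 0.56 over 25 genes (percentile 86.1), with the integrin linker Tln1 at 1.31, the intermediate filament Vim at 0.92 and Actb, a common reference gene, at 0.02. The proteasome had 0.40 over 31 genes (percentile 86.7), led by the immunoproteasome subunit Psmb9 (733 to 1374, 1.21). MHC class I had 0.34 over 7 genes (percentile 84.3), with H2-K1 at 0.81 and B2m from 418 to 494 (0.54). Translation factors had 0.38 over 26 genes (percentile 77.6), negative with quantile normalization, with Eif3h at 0.97 and Eif1a at -0.92. Against random lists not matched on level, the cytoskeleton (percentile 99.98), the proteasome (99.3) and translation factors (98.8) lay above the range.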

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

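All alternatives here were planned and 0 were added after the data were seen. Against 390 genes higher and 175 lower, counts were 121 and 579 as deposited, 253 and 286 with quantile normalization, 247 and 284 with loess, 701 and 380 without the filter on dim genes, 168 higher with a pseudocount, 92 lower with the stricter filter, and 10 and 0 with the 4-fold rule (5 and 7 by that rule as deposited). The first of these follows from leaving out the shift between arrays, and the filter and the 4-fold rule change counts by construction. The cause of the others was not tested. Of the 390 higher genes, 121 were shared with the deposited values, 241 with quantile normalization and 242 with loess, and all 175 lower genes were shared with each of these. For the deposited values this was fixed by the constant shift. Quantile normalization and loess also moved the median difference of kept genes down, from 0.08 to 0.00. The sharing of lower genes is therefore no sign that they are robust. With a pseudocount 168 of the higher and 92 of the lower genes were shared (127 lower in all), and with the stricter filter 293 and 92. Pearson's r across genes was 0.962 without the filter, 0.960 with the stricter filter and 0.961 with a pseudocount, and Spearman's rho 0.943 without the filter and 0.919 with the stricter filter; the cause was not tested. Of list medians, 194 stayed within their spread and 47 moved beyond it, and of differences of named genes 1181 stayed and 11 moved. Part of the list tally was also fixed in advance. Of the 47 moved medians, 21 came from the values as deposited, a constant shift. Of the 194 that stayed, 35 came from the brightest probe, which could change only the 358 kept genes with several probes. Most of the named-gene outcomes were fixed in advance. A filter cannot change a gene's difference, and the brightest probe changes it only for genes with several probes. The deposited values move each gene by the same -0.30, so this tally says little about single genes. Of the 25 lists inside the random range, 7 had a median that changed sign with quantile normalization or loess, and a further 4 only with the values as deposited, which moves every gene by the same amount. B cell markers had too few genes for a percentile with the stricter filter. Dim genes limit precision, as the SD of differences was 0.74 among the 10% of kept genes with the lowest level.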

Other observations

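Tests chosen only after the result was seen were the loess tests of the MHC class II and respiratory chain genes, the scaling test of globin genes, the B cell list without MHC class II genes, and the use of a list's own spread in reading the B cell and red cell genes. The background and red cell tests were set aside only after their values were seen.

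Several further gene groups stayed inside the random range. NK cell markers had a median of 0.46 over 5 genes (percentile 89.4), with the receptors Klra8 (151 to 244, 0.99) and Klrd1 (0.63) ahead. Neutrophil, mast cell and basophil markers had a median of 0.26 over 5 genes (percentile 81.1), negative as deposited. Apoptosis genes had 0.16 over 7 genes (percentile 59.9), negative as deposited, with Casp8 at 0.52 and the survival factor Mcl1 at -0.50. Heat shock and unfolded protein response genes had -0.07 over 17 genes (percentile 9.78), although the stress factor Ddit3 went from 214 to 403 (1.21). Nuclear long noncoding RNAs had 0.10 over 6 genes (percentile 48.4), negative as deposited and with loess. Among them Rmrp, the RNA of an RNA-processing enzyme, went from 53 to 96 (1.16). Malat1, a nuclear RNA, had a mean difference of 1.21 over a pair of probes that disagreed, and 0.17 by its brightest probe.

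Tissue markers unrelated to T cells gave fibroblast and endothelial genes a median of -0.01 over 6 genes (percentile 43.6), liver genes -0.15 over 6 (percentile 25.7), neuronal genes -0.12 over 9 (percentile 19.7) and keratins 0.02 over 40 (percentile 36.4), the last negative under the other scalings. Zinc finger genes named Zfp had -0.05 over 111 genes (percentile 4.70), below the random range with quantile normalization (1.86), a pseudocount (1.42) and random lists not matched on level (1.93). Helper and regulatory T cell markers kept 4 genes, too few for a percentile, with the chemokine receptor Ccr6 from 38 to 71 (1.20) and Cd4 from 40 to 25 (-0.38). Endogenous retroviral genes kept 2, with Rtl1 from 78 to 27 (-1.23). Mitochondrially encoded genes had 0 probes. A value on the 0.3 M array alone was found for 2213 genes, the brightest being Htr3a (41), Gatad2b (38) and Ajm1 (31), and on the 0.5 M array alone for 456, the brightest being Nat8f1 (39), Cd40lg (36) and Ly6k (21). Since the reason for empty cells is not known, no fold is given. Of 949 kept probes without a symbol, 65 were at least 2-fold higher and 21 lower.

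MHC class II and B cell genes had a joint median of 2.09 over 9 kept genes of 14 measured, 7 of them at least 2-fold higher at 0.5 M. Members left out as dim were Cd79a (15 to 11), Fcer2a (19 to 12), H2-Ab1 (13 to 15), Ms4a1 (21 to 21) and Vpreb3 (12 to 12). None of these was 2-fold higher. Blnk and Ciita passed the filter only by their value at 0.5 M. A trend with intensity as the whole cause was argued against by its size, a median difference of at most 0.46 in any 10% of kept genes by level. After loess 7 of the 9 were still at least 2-fold higher (percentile 100, median spread -0.23 to 2.29). That percentile carries no weight, since the joint list was formed from these results and holds H2-Ea, which no list fixed in advance holds. RNA of B cells may contribute but stays open. Further B cell genes lay at percentile 99.8 (11 kept of 22 measured), past the bound written beforehand. The spread of their median (-0.22 to 1.16) held the random value of 0.08. Napsa, Cd40 and H2-DMa (24 to 52), all at least 2-fold higher, passed the filter only by their value at 0.5 M. The filter thus favoured that percentile, and none without the filter was computed. Without MHC class II genes the percentile was 92.3, with 4 of 8 genes above 0 and 4 below. Above were Napsa (17 to 33), Cd40 (24 to 40), Spib (33 to 53) and Cd52 (2058 to 3727), which T cells also express. Below were Cd180 (250 to 161), Syk (98 to 60), Swap70 and Ltb, which T cells also make. Macrophage or dendritic cell RNA stays open too. Further genes of these cells lay at percentile 88.8, with 12 of 15 above 0 after centring and 10 with loess. Intensities rose for Ifi30 (29 to 52), Cst3 (183 to 292), Batf3 (135 to 169), Lgals3 (744 to 1380) and Ctsd (959 to 1197). Activated T cells also make Lgals3, and most cells make Ctsd. The rest of those above 0 did not rise as deposited, such as Aif1 (125 to 105), Plbd1 (38 to 31) and Ctsb (45 to 45). Below 0 were Trem2 (68 to 31), Csf2ra (40 to 23) and Clec4n (79 to 62). The labels name no sort, and a difference between vesicle types that elute at different salt was not tested apart from these.

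Respiratory chain genes were higher at 0.5 M with a median of 0.68. An intensity trend as the whole cause was argued against by a percentile of 100 after loess. A higher additive background on the 0.3 M array was tested on the 34 members in the brightest 10% of kept genes, which lay at percentile 94.2, the side this explanation needs by the bound written beforehand, but that test decides nothing, because after centring such a background raises the brightest genes most and the random lists were already matched on level. A background that is uniform over the array acts as a trend with intensity, so the loess value bears on it. After loess the same 34 members lay at percentile 99.25 (median 0.42). An uneven background stays open. A difference in vesicle content between the salt fractions stays open and untested.

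Globin genes were lower at 0.5 M. Scaling as the cause was argued against, since their median relative to all kept genes was -0.80 with centring, -1.14 with quantile normalization and -1.11 with loess. Less red cell RNA at 0.5 M stays open. Further red cell genes lay at percentile 64.3 (14 genes, median 0.13), past the bound of 50 written beforehand against this source. The spread of their median (-0.09 to 0.39) lay wholly above the -0.27 that this source needed. Of those genes Fech, Urod, Uros (-0.34), Alad, Ppox, Cat (-0.89), Prdx2 (1101 to 1605) and Blvrb are expressed in most cells, T cells included, and the other 6, more specific to red cells and mostly dim, were Hemgn (0.26), Epb42 (0.18), Gypc (0.16), Kel (0.08), Gata1 (-0.03) and Sptb (342 to 254, -0.13), none as low as the globins. Genes that T cells make, or that are dim, could hide a loss of red cell RNA, so this list decides nothing. A source that brings globin RNA with little else, serum in the medium and vesicle type were not tested.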
